A study of Mus musculus with 2 samples.

How the data were processed

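MicroRNA sequencing libraries of the embryonic facial prominences of mouse strain B6NCrl at embryonic day 14.5 were analysed, 1 from each of 2 biological replicates. The labels describe both samples as a single face of one pup, collected on different days, and also give the sex as a pool of male and female. Whether a replicate is 1 embryo or a pool is therefore not settled, and the replicates are treated as separate samples of one group. The day of collection and the replicate coincide and cannot be separated.

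The deposited values are raw read counts per miRNA gene, with 1 library per file and no pooling of replicates. Reads were aligned to assembly mm10 and counted over the miRNA genes of GENCODE M4, per the labels and the metadata text deposited beside the counts. The aligner, its settings and the adapter trimming are not given in the sources used here. Each file holds 1973 gene rows, 4 summary rows for reads not assigned to a gene, and 3 count columns. The column names are absent, and the layout is that of STAR gene counts, in which the columns hold both strands together, the strand of the gene and the opposite strand. In every gene row the last 2 columns sum to the first. In this layout only reads with a single position in the genome are counted, so reads of miRNAs with several near-identical copies fall into the summary row for multiple positions.

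The gene-strand column, which held most miRNA counts, was the main measurement. Replicate 1 had 5617037 reads, of which 2719153 (48.4%) were assigned to miRNA genes on the gene strand. Replicate 2 had 13380839 reads, of which 6602050 (49.3%) were so assigned. Unmapped reads made up 16.6% and 17.6%, reads at several positions 29.8% and 28.5%, uniquely placed reads outside miRNA genes on either strand 3.00% and 2.38%, reads on the opposite strand of miRNA genes 2.23% in each, and reads assigned ambiguously 0 in each. The summary rows were left out of library sizes and tests. A count of 0 allows up to 3 counts, which is 1.10 CPM (counts scaled to a common library total) in replicate 1 and 0.454 CPM in replicate 2. Molecular identifiers are not described, so intervals and floors cover counting error only.

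Symbols, positions and gene context were taken from GENCODE M21 on the same assembly, matched by gene identifier. Of the 1973 identifiers 1894 had a name, 1815 of them with the same version, and 2 of the unnamed ones had a count. GENCODE M21 holds 2202 miRNA genes, of which 308 have no row in the files. A gene was called intronic or exonic where it lay in an intron or exon of a gene that is not a miRNA gene.

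CPM was computed over the gene-strand miRNA counts of each library and given as mean and SD of the 2 replicates. With 1 group there is no contrast between conditions. For each gene with a mean of at least 10 counts, an exact two-sided binomial test compared the counts of the 2 libraries, given their sum and the TMM effective library sizes of edgeR 4.0.16. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05, and log2 ratios, replicate 2 over replicate 1, used a prior of 0.5 counts. This test compares 2 libraries, not conditions. The biological coefficient of variation was taken from the common dispersion of edgeR with an intercept only. Correlations across genes used log2 of CPM plus 1.

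Before the data were examined, 29 lists of miRNAs were fixed, covering families, genomic clusters and markers of cell types the tissue could hold. Of their 233 members 217 had a row. For the 26 lists with at least 3 tested members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. A permutation test with 100000 shuffles asked whether members of one genomic cluster share their difference between the replicates. Named genes are the 20 with the highest mean CPM, the 2 highest members of each list, and the 5 with the largest log2 ratio in each direction among those past the binomial test with a mean of at least 100 CPM. Other genes named below were chosen after their values were seen.

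The binomial step was tested on counts simulated for the 372 tested genes of these 2 libraries, with Poisson counting error only, as the test itself assumes. The rates below therefore leave out any spread between libraries beyond counting. The test called 1.16% of unchanged genes, 49.0% of genes changed 1.2-fold, 71.1% at 1.5-fold, 86.5% at 2-fold and 100% at 4-fold. Alternatives fixed beforehand were the unstranded column, total counts and DESeq2 1.42.0 size factors in place of TMM, other count filters, other pseudocounts and priors, leaving out the highest gene or the Dlk1-Dio3 cluster, thinning to equal depth, and leaving out each replicate. Added after the data were seen were a removal of the GC trend, lists and clusters without genes that share a 20-base stretch with another miRNA gene, the list medians with each genomic cluster counted as 1 unit, and the marker ratio without Mir203. GC content was that of the annotated precursor, not of the reads. Computations used R 4.3.3, Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3.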

Results

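Small RNA was profiled in the facial prominences of mouse embryos at day 14.5. These tissue buds, made of mesenchyme under an epithelium, form the face and jaws. There were 2 biological replicates and no other group, so the values describe the miRNA content of one tissue and the spread between its replicates. Gene-strand miRNA counts were 2719153 in replicate 1 and 6602050 in replicate 2. In both libraries together 717 miRNA genes had at least 1 count, 350 had at least 10 counts in each library, 202 had a mean of at least 100 CPM and 102 of at least 1000 CPM.

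A small set of miRNA genes made up much of the uniquely placed miRNA counts of the tissue. Reads mapped to several sites, 29.8% of all reads in replicate 1 and 28.5% in replicate 2, are not in these counts. Mirlet7i, a member of the let-7 family that accumulates as tissues differentiate, was highest at 78025 ± 7034 CPM (mean ± SD, n = 2). Its share was 7.31% in replicate 1 (95% Wilson interval 7.27 to 7.34) and 8.30% in replicate 2 (8.28 to 8.32). Mir99a followed at 67454 ± 6112 CPM, Mir335 at 51763 ± 7238 CPM, Mir126a at 47919 ± 8833 CPM, Mirlet7g at 40899 ± 4232 CPM and Mir140 at 40087 ± 1018 CPM. Mir335 lies in an intron of the imprinted gene Mest, Mir126a in the endothelial gene Egfl7, and Mir140 in Wwp2, a gene active in cartilage. The 10 highest genes, which also included Mir322, Mir23b, Mir203 and Mir130a, held 44.7% ± 1.42 of the counts (43.7% and 45.7%). Of the 10 highest genes of each library 9 were shared, and 18 of the 20 highest.

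On assembly mm10, Mirlet7i (ENSMUSG00000065406.2) lies on chromosome 10 at 122985640 to 122985724, minus strand, in an exon of the noncoding gene D630033A02Rik. Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 at 77598936 to 77599000, plus strand, in an intron of Mir99ahg. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 at 30741299 to 30741396, plus strand. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 at 26591357 to 26591429, plus strand, and Mir140 (ENSMUSG00000065439.1) on chromosome 8 at 107551244 to 107551313, plus strand.

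**Figure D1:**
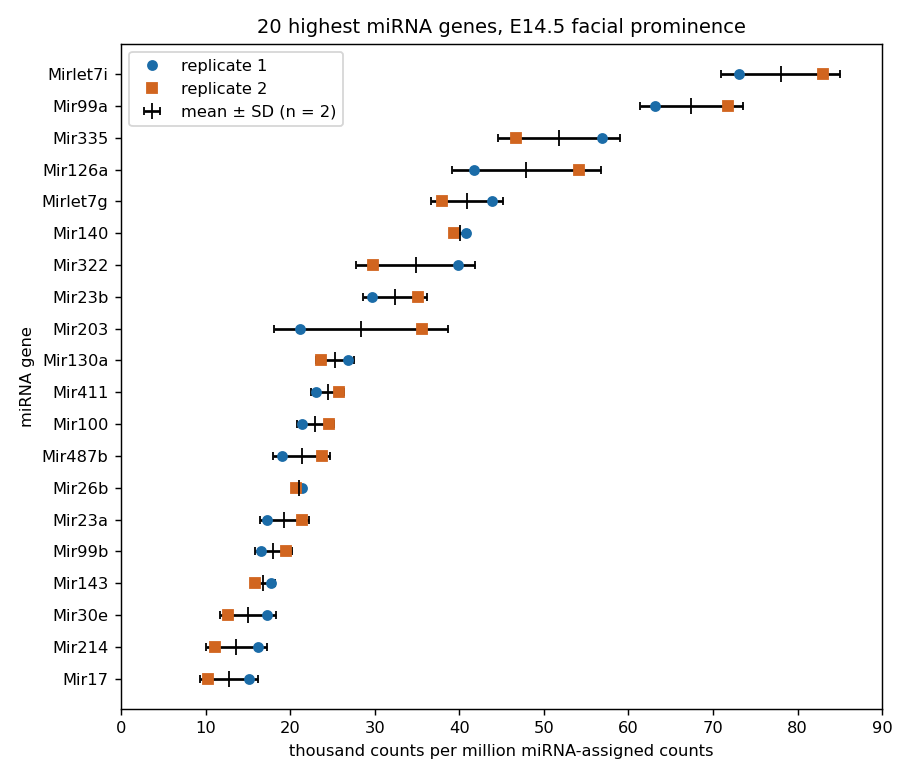
CPM divided by 1000 (linear axis) of the 20 miRNA genes with the highest mean, with a circle for replicate 1, a square for replicate 2, and a bar for mean ± SD (n = 2). Mirlet7i leads at 78025 CPM, and Mir203 has the widest bar, 28346 ± 10257 CPM.

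The let-7 family summed to 140555 ± 4263 CPM, and Mirlet7i was 55.5% of it. Of the 10 let-7 genes with a row, 5 share a 20-base stretch with another miRNA gene, so their reads can be lost as multiply mapped. The miR-99/100 and miR-125 set summed to 116608 ± 10252 CPM, with Mir99a and Mir100 (22975 ± 2237 CPM) as its highest members. The imprinted Dlk1-Dio3 cluster, a large maternally expressed miRNA cluster, held 12.8% of the counts in each library, spread over many genes. Mir411 (24405 ± 1935 CPM) and Mir487b (21350 ± 3343 CPM) were its highest members, and 44 of its 49 genes with a row were detected. Its sum of 128170 ± 42.2 CPM leaves out Mir409, Mir376a, Mir299a and Mir380, whose sites carry 22317 CPM equivalent in the opposite-strand column. With such reads added, the cluster would stand at 150488 CPM equivalent and let-7, whose Mirlet7e has no row, at 145675. Both are scaled to the gene-strand total, and a total that also held the added reads would give lower values. The miR-232724 clusters summed to 55704 ± 6269 CPM, led by Mir23b (32381 ± 3777 CPM) and Mir23a (19301 ± 2878 CPM). The miR-15/16 family reached 45776 ± 6992 CPM, 76.0% of it from Mir322 of the X-linked Mir322 to Mir503 cluster, whose own sum was 44745 ± 6776 CPM.

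The growth-associated miR-17~92 cluster and its paralogues summed to 30321 ± 8760 CPM, led by Mir17 (12715 ± 3450 CPM) and Mir93 (4162 ± 1279 CPM). The miR-130 and miR-301 family stood at 30724 ± 3106 CPM, with Mir130a at 25247 ± 2260 CPM. The miR-30 family reached 23159 ± 4059 CPM with Mir30e at 14976 ± 3279 CPM, and the miR-26 family 21113 ± 461 CPM, 99.7% of it from Mir26b. Lower sums were found for the miR-181 family (10015 ± 1124 CPM, led by Mir181c), the miR-148 and miR-152 family (2391 ± 69.3 CPM, led by Mir148a) and the miR-29 family (243 ± 39.1 CPM, led by Mir29a). In the miR-26 family 2 of 3 members, in the miR-29 family 3 of 4 and in the miR-181 family 4 of 6 share a 20-base stretch with another miRNA gene. Their reads can be lost as multiply mapped, which can lower these sums and raise the share of Mir26b.

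Markers of the cell types that build the face were present at very different levels. The epithelial miRNAs summed to 59942 ± 10596 CPM, with Mir203, a miRNA of differentiating epidermis, at 28346 ± 10257 CPM and Mir429 of the miR-200 family at 11362 ± 754 CPM. The mesenchymal set summed to 14881 ± 3906 CPM, 91.4% of it from Mir214 (13601 ± 3584 CPM), with Mir199b at 961 ± 289 CPM. Cartilage markers reached 42578 ± 1238 CPM, 94.1% of it Mir140, with Mir455 at 2491 ± 220 CPM. Endothelial Mir126a was the only member of its list with a row. Muscle was marked by Mir206, a skeletal muscle miRNA, at 12271 ± 1164 CPM, 94.7% of the striated muscle sum of 12960 ± 1095 CPM, in which the copies of Mir133a and Mir1a, which share sequence, are near 0. Smooth muscle markers summed to 17204 ± 1309 CPM, 97.7% of it Mir143.

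The sensory organ cluster, active in hair cells and other sensory cells, summed to 19530 ± 1224 CPM, with Mir182 at 9837 ± 75.7 CPM and Mir183 at 6575 ± 693 CPM. Hox-cluster miRNAs reached 10244 ± 2070 CPM, led by Mir10b (6102 ± 50.8 CPM) and Mir10a (3457 ± 1233 CPM). Multiciliated cell markers summed to 4036 ± 1484 CPM, 82.7% of it Mir449a. Neural markers stood at 1812 ± 247 CPM, with Mir137 at 631 ± 154 CPM and Mir338 at 193 ± 1.39 CPM. Of the 20 neural genes with a row, 15 share a 20-base stretch with another miRNA gene, but Mir137 and Mir338 do not. Loss of multiply mapped reads can therefore lower the neural sum and put these genes first. Pituitary and endocrine markers reached 1262 ± 312 CPM, 78.5% of it Mir375, and erythroid markers 1249 ± 221 CPM, 91.0% of it Mir451a. Leukocyte markers summed to 811 ± 118 CPM, led by Mir223 at 626 ± 118 CPM, but Mir142 has no row. With its 829 CPM equivalent from the opposite-strand column Mir142 would lead the list, at a sum of 1639.95 CPM equivalent on the gene-strand total. Eye and choroid markers stood at 737 ± 251 CPM, led by Mir204. Liver, gut and exocrine pancreas markers summed to 169 ± 14.9 CPM and the pluripotency clusters to 161 ± 41.2 CPM, led by Mir192 and Mir302a.

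Levels of different miRNAs carry the biases of adapter ligation, and multi-copy miRNAs are under-counted because only uniquely placed reads enter. The 71 listed genes that share a 20-base stretch with another miRNA gene had a median of 48.8 CPM, against 635 CPM for the other 146 (two-sided permutation test across genes, p = 2e-05, chosen after the data were seen).

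Mesenchymal markers were below epithelial markers in both libraries. The log2 ratio of the sums was -1.57 in replicate 1 and -2.48 in replicate 2, a mean of -2.02 ± 0.64 (SD, n = 2). Without Mir203 the mean ratio was -1.11, and 3 of the 4 mesenchymal genes but 0 of the 7 epithelial genes share a 20-base stretch with another miRNA gene, so their reads can be lost as multiply mapped. With 2 libraries the smallest exact p is 0.5, so no exact test of the marker sets can pass 0.05.

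The replicates ranked the miRNA genes alike and yet differed at many single genes beyond counting noise. Across the 372 tested genes, Pearson's r was 0.992 and Spearman's rho 0.990, with genes not being independent replicates, and the biological coefficient of variation was 20.9%. Of the 202 genes with at least 100 CPM, 187 (92.6%) lay within 1.5-fold and 3 differed at least 2-fold. The exact binomial test called 194 genes, 102 higher and 92 lower in replicate 2. With total counts in place of TMM the split was 64 higher and 133 lower, because TMM raises the median log2 ratio by 0.12. Of the called genes, 16 were at least 1.5-fold higher and 21 at least 1.5-fold lower in replicate 2.

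Among called genes with a mean of at least 100 CPM, the largest difference was in Mir196b, which lies in an exon of Hoxa9 on chromosome 6 at 52230081 to 52230165, minus strand. It stood at 1044 CPM in replicate 1 (2839 counts) and 35.9 CPM in replicate 2 (237 counts), a log2 ratio of -4.73 with a counting SE of 0.10. The Hox-cluster genes Mir615 (-0.98) and Mir10a (-0.62) and Mir106b (-0.60) and Mir18 (-0.60) of the miR-17~92 group were the next lower in replicate 2. Highest above replicate 1 was Mir1298, in an intron of the serotonin receptor gene Htr2c on chromosome X at 147064905 to 147065002, plus strand, at 55.5 CPM and 222 CPM (log2 ratio 2.12, counting SE 0.12, exact binomial test with Benjamini-Hochberg adjusted p = 1.31e-95). Mir449a (1.02), Mir92b (0.96), Mir204 (0.91) and Mir203 (0.88) followed. Among the other named genes the differences in each direction were smaller, and among the called ones the direction of Mir140, Mir26b, Mir182, Mir10b and Mir148a turned when total counts replaced TMM.

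**Figure D2:**
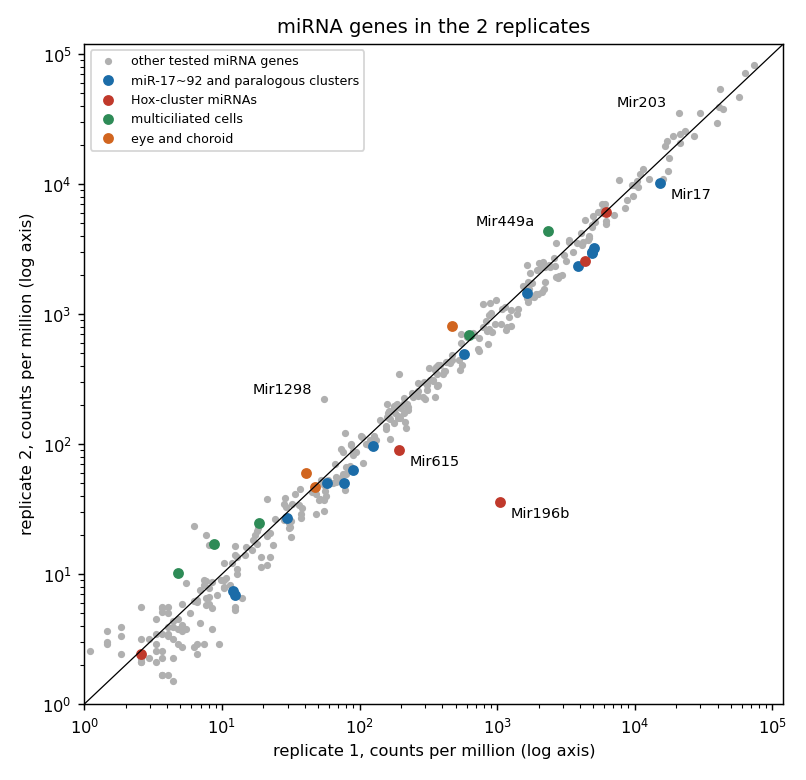
CPM of the tested miRNA genes in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with members of 4 lists coloured and a line of equality. Mir196b lies far below the line at 1044 and 35.9 CPM.

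Of the 26 lists, 7 had a median log2 ratio outside the central 95% of matched random lists. Random lists draw genes singly, while members of one genomic cluster tended to share their difference, so this range is too narrow for lists made of clusters. With each cluster counted as 1 unit, an alternative chosen after the data were seen, 2 of the 19 lists with at least 3 units lay outside, the Hox-cluster list (percentile 0) and the eye and choroid list (percentile 100). In both, every tested member was its own unit, so their medians did not change and the alternative was no stricter check of them. Mir615 and Mir196a-2 of the Hox-cluster list lie in introns of the same gene, Hoxc5, and were still counted apart. The miR-17~92 clusters were lower in replicate 2: 8 of 14 tested members were lower, 9 when adjusted over the list alone and 11 with total counts, and 6 did not pass the test over all genes. Their median was -0.47, at percentile 0 over single genes and 6.42 over 3 cluster units, whose median was -0.38, with Mir17 at -0.44 and Mir93 at -0.51. The shift was uneven within clusters. Mir92-1 of the Mir17 cluster (-0.036, 4465 and 9691 counts) and Mir25 of the Mir93 cluster (-0.089, 1558 and 3261 counts) did not pass the test over all genes despite their counts. This depends on the scaling: with total counts their log2 ratios were -0.16 (counting SE 0.026) and -0.21 (counting SE 0.044). All 5 multiciliated markers were higher in replicate 2, 4 of them past the test with total counts, with a median of 1.02 at percentile 100, or 0.51 at percentile 99.2 at a mean of at least 100 counts, Mir449a at 1.02 and Mir34c at 0.28. They form 2 cluster units, too few for a percentile over units, so that percentile holds for single genes only. Eye and choroid markers had 2 of 3 members higher (median 0.69, percentile 100), namely Mir204 at 0.91 and Mir211 at 0.69. Pituitary and endocrine markers had 2 of 4 higher (median 0.36, percentile 97.65, and 94.87 over units with the same median), with Mir375 at 0.74 and Mir7b at 0.48.

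The Hox-cluster list had 3 of 5 tested members lower and Mir10b higher (median -0.62, percentile 0), and -0.24 at percentile 7.88 with no count filter, when Mir196a-1 enters with 3 counts in all. The direction of Mir10b turned with total counts. The X-linked Mir322 to Mir503 cluster had 3 lower and 1 higher of 7, Mir322 at -0.29 and Mir351 at 0.42 (median -0.29, percentile 2.22). Its lower members numbered 5 with total counts, and its percentile was 3.58 with the unstranded column, 3.93 with no count filter, 4.23 at a mean of at least 100 counts and 24.89 (median -0.11) without genes sharing a 20-base stretch. In the miR-232724 clusters 3 of 5 were higher and 1 lower (median 0.36, percentile 98.98 over single genes). The X-linked list is 1 unit and this list 2, so neither has a percentile over units, and all 5 members of this list share a 20-base stretch, so none is left without such genes. Adjusted over the list alone, the calls of the other lists were the same as over all genes, except for 3 lower in the miR-15/16 family instead of 2, 2 lower in the miR-29 family instead of 1, and the pluripotency clusters.

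The remaining 19 lists with a percentile lay inside the central range. In the let-7 family 9 of 10 members were higher, 5 of them past the test with total counts, and Mirlet7g was lower (median 0.24, percentile 96.44). In the epithelial list 5 of 7 were higher, of which Mir200c turned with total counts, and 1 was lower. In the mesenchymal list 2 of 4 were lower, and 3 with total counts, with Mir214 at -0.42 and Mir199b at -0.50. The Dlk1-Dio3 cluster had 17 higher and 17 lower of 44, and 11 higher and 21 lower with total counts. In the miR-130 and miR-301 family 3 of 4 were lower. In the miR-99/100 and miR-125 set 4 of 6 were higher, 3 with total counts, in the sensory list all 3, of which Mir182 turned with total counts, and in the erythroid list 2 of 3, of which 1 passed the test with total counts. In the pluripotency clusters 3 of 6 were lower over all genes, 5 when adjusted over the list alone and 5 with total counts (median -0.40, percentile 2.91).

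**Figure D3:**
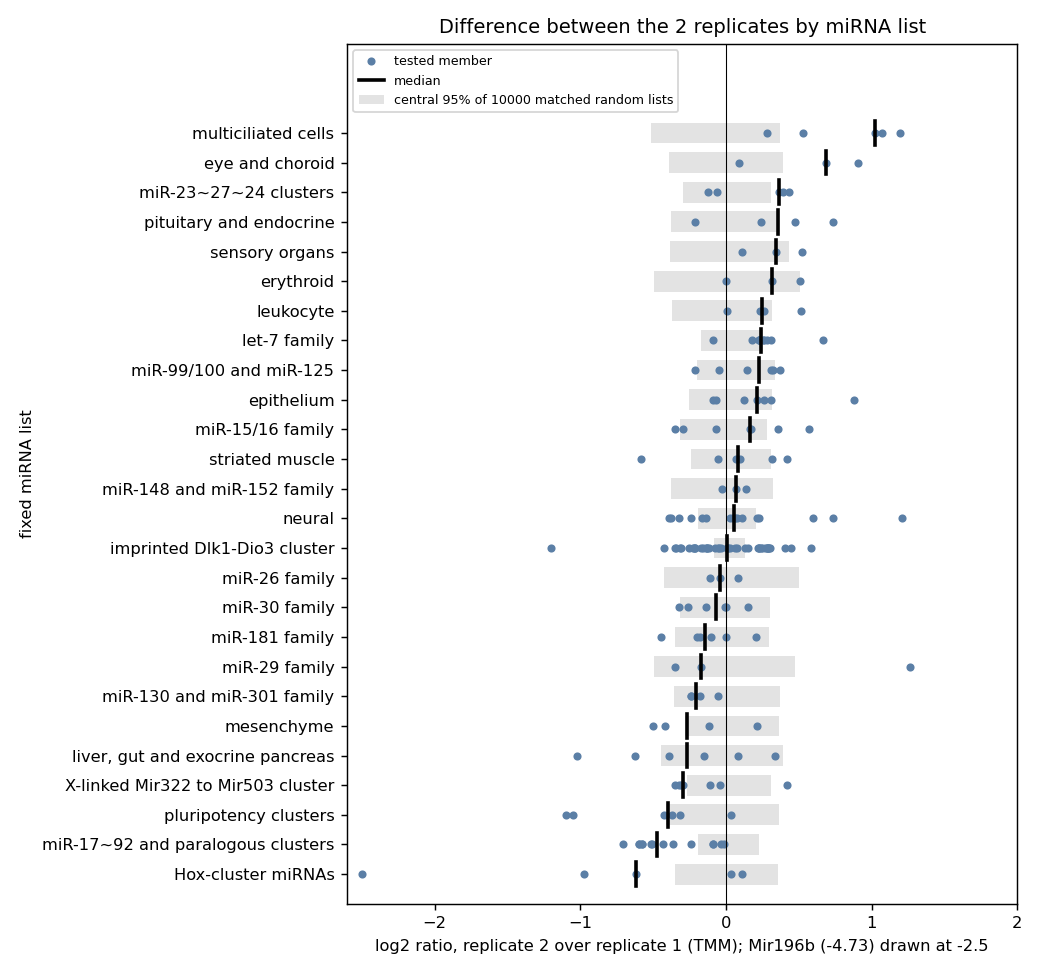
Log2 ratio, replicate 2 over replicate 1 (TMM, horizontal axis), of each tested member (points) and the median (bar) of each of the 26 lists, with the central 95% of matched random lists in grey. Mir196b (-4.73) is drawn at the left edge, not to scale. The multiciliated median (1.02, no percentile over units) and the miR-17~92 median (-0.47) lie outside the grey range, which is drawn for single genes.

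Genes of one genomic cluster tended to share their difference between the replicates. Among 37 clusters with 137 tested members, cluster membership took 56.5% of the sum of squares of the log2 ratios (one-sided permutation test across genes, p = 1e-05, the smallest that 100000 shuffles can give). Shuffled ratios also give a share above 0, and its mean was not recorded. The largest cluster, Dlk1-Dio3, was an exception: its 44 tested members ranged from -1.20 to 0.58 around a mean of -0.00062. Without that cluster the share was 71.5%. In 23 clusters all tested members lay on one side of 0, as in the 3 tested members of the miR-449 cluster. Most clusters have only 2 tested members, which often share a side by chance, and no expected number was computed. The miR-449 cluster had the largest mean log2 ratio, 1.09, and no alternative left it out. Counted levels within a cluster ranged widely, with a median of 20.8-fold between the highest and lowest member and at least 10-fold in 23 clusters. Part of this range can come from reads lost as multiply mapped. Mirlet7c-1, lowest in the Mir99a cluster (456-fold), and Mir30c-1, lowest in the Mir30e cluster (252-fold), share a 20-base stretch with another miRNA gene. Mir449b, lowest in the miR-449 cluster (447-fold), shares none. With no count filter the share was 37.5% (permutation p = 0.0795).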

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

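The test of the opposite-strand reads was chosen after those reads were seen. In each library 2.23% of all reads fell on the opposite strand of miRNA genes, a column outside the main measurement, and 19 genes had over 3 such counts in each library. The highest were Gm25301 at 13728 CPM equivalent (scaled to the gene-strand total), Gm24321 at 8252, Gm25252 at 7421, Gm25927 at 5120, Mir299b at 3679, Gm25750 at 2965, Gm24083 at 2663, Mir142b at 829 and Mir497b at 678. All 9 overlap a miRNA gene on the other strand in the later annotation, against 9 of 199 other genes with at least 1000 gene-strand counts over both libraries (Fisher's exact test, p = 2.885e-11). These partners, Mir378a, Mir409, Mir376a, Mirlet7e, Mir299a, Mir380, Mir191, Mir142 and Mir497, have no row of their own, so a miRNA gene on the other strand of the same site is a likely source of the 9 signals; no biological explanation was tested. In CPM the loss is largest for the Dlk1-Dio3 sum (22317 CPM equivalent from 4 partners), and against a list's own sum it is largest for the leukocyte list (829 CPM equivalent of Mir142 beside 811 CPM counted). The let-7 family lacks Mirlet7e and the miR-15/16 family Mir497.

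Reads mapped to several sites, which no miRNA gene row holds, made up 29.8% of replicate 1 and 28.5% of replicate 2.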

How the results depend on the processing

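The alternatives that removed the GC trend, the genes sharing a 20-base stretch or Mir203, or counted each cluster as 1 unit, were chosen after the data were seen. Over all results and alternatives, 1043 values stayed within the spread or kept their call, 43 moved, 17 lost and 8 gained a call, and 6 called values, all of single genes, reversed. Part of the values that stayed could not have moved. Leaving out a replicate always shifts a mean level by less than the SD of the replicates. Another scaling cancels in the marker ratio and shifts all log2 ratios nearly alike, which leaves list percentiles and the cluster share almost unchanged. The tally is therefore no measure of robustness. Uncalled values that changed sign but stayed uncalled are counted as kept: 11 list medians under single alternatives, from 7 lists, and 6 log2 ratios of 5 genes. Among them were the neural list (0.056, and -0.15 at percentile 6.87 at a mean of at least 100 counts), the miR-29 family (-0.17, and 0.13 with no filter), the miR-15/16 family (0.16, and -0.069 without shared stretches) and striated muscle (0.082, and -0.043 with total counts). The number of detected genes ranged from 329 (thinned to equal depth) to 439 (at least 3 counts), and the number of genes called between the replicates from 176 with no filter to 204 with the unstranded column. Over alternatives changed 1 at a time, the biological coefficient of variation ranged from 20.5% to 21.7%. The share of the 10 highest genes was 42.7% with the unstranded column and 42.7% without Mirlet7i in the total. The mesenchyme to epithelium log2 ratio was -1.11 without Mir203, which carries much of the epithelial sum. The cluster share was 37.5% with no count filter, which adds genes with few counts. With total counts the log2 ratio reversed for Mir140 (-0.052), Mir26b (-0.044), Mir182 (-0.016), Mir10b (-0.017) and Mir148a (-0.054), and with no filter, whose TMM factors raise log2 ratios by 0.047, for Mir143 (0.012). Both are shifts of the scaling. The number of lists outside the central range lay between 5 of 20 without genes sharing a stretch and 8 of 26, but was 2 of 19 with each cluster as 1 unit, where lists with under 3 units gave no value. The 8 calls gained were let-7 with no filter (percentile 97.57), the unstranded column (97.64) and the GC trend removed (97.65), the pluripotency clusters with a prior of 5 counts (2.15) and without shared stretches (1.35), Mir152 with total counts (log2 ratio -0.15), and Mir29a with total counts (-0.30) and at a mean of at least 100 counts (-0.19). Of the list calls lost, that of the X-linked Mir322 to Mir503 cluster moved furthest inside the range, to percentile 24.89 without genes sharing a stretch. Depth limits genes near the floor of 3 counts.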

Other observations

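Of the 350 detected miRNA genes, 152 lay in introns of other genes and held 40.3% of the counts in replicate 1 and 39.2% in replicate 2. A further 108 were intergenic, with 28.9% and 29.3% of the counts, and 90 overlapped exons, with 30.8% and 31.5%. Mir26b in Ctdsp1, Mir30e in Nfyc, Mir181c in Nanos3, Mir455 in Col27a1 and Mir204 in Trpm3 were among the intronic genes. Mir124a-1, Mir124a-2 and Mir124a-3, copies of a neuronal miRNA with shared sequence, had 0 counts in both libraries, which at 3 counts allows up to 1.10 and 0.454 CPM of uniquely placed reads.

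The tests below were chosen after the patterns they address were seen. Mir196b was higher in replicate 1 by a fold with an exact 95% interval of 23.34 to 30.57, which counting noise alone cannot give. Reads leaked from libraries of other tissues cannot be told apart, because the liver, gut and pancreas list lay at percentile 11.37, between the bounds set for and against it. That list marks only these organs, so it could not decide on a leak from any other tissue. Trunk or limb tissue in the replicate 1 dissection may also have raised Mir196b, and stays open because 2 of the 4 other tested Hox-cluster genes were lower in replicate 2 and the others were not. Of those others, Mir196a-2 had only 7 and 16 counts (counting SE 0.65), too few to decide, and the direction of Mir10b turned with total counts.

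The miR-17~92 clusters, with a median of -0.47, kept -0.46 after a linear trend in GC content was removed and -0.51 over the 11 members that share no 20-base stretch, each at percentile 0 over single genes. Across genes the log2 ratio followed precursor GC content only weakly (Spearman's rho 0.13), so removing a linear trend could move the median little. The medians argue only against a linear effect of precursor GC content, and against shared precursor reads, as the whole cause. GC content of the sequenced mature miRNAs was not tested. The 3 clusters as units (median -0.38, percentile 6.42) leave chance open at a similar size. More epithelium in replicate 2 may contribute and cannot be told apart, since the epithelial list lay at percentile 86.05, between the bounds set. A later stage of the replicate 2 embryo cannot be told apart either, with let-7 at percentile 96.44 and the pluripotency clusters at 2.91, and no alternative run took both past their bounds. The design has 1 group and names no biological difference, and the day of collection coincides with the replicate.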
